A study of Mus musculus with 12 samples.

How the data were processed

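Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in 12 mouse libraries of 4 cultured cell types. The labels give 4 libraries of embryonic stem cells (ESC), 3 of trophoblast stem cells (TSC), 2 of XEN cells and 3 of EPISC, which the labels call epiblast-like stem cells. Each reaction used 50000 cells and a transposition of 30 min at 37 °C, per the labels' protocols. The ESC libraries carry the words "ad" and "new" in their titles, whose meaning is not given in the sources used here. The description of the last TSC library calls it replicate 2, the growth protocol gives 2 replicates per line, and the EPISC descriptions name a list spelled differently from the EPISC list used.

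The files used here hold 1 list of accessible regions per cell type, each with a chromosome, a start and an end, and no score, read count or value per library. Bowtie2 2.3.4.1, Picard, bedtools and MACS2 and the build mm10 are named, per the submitters' processing notes. The order and settings of these tools, any shift of reads for the transposase's offset, the depth per library and the way libraries were combined are not given in the sources used here. The ESC, TSC and XEN lists were found to be subsets of 1 catalogue of 98017 regions, in which overlapping regions of any pair had identical coordinates. The EPISC list was not drawn from this catalogue: it shared at most 2 regions with identical coordinates with any other list, its median width was 254 bp against 170 to 193 bp, and 9567 of its regions overlapped 2 or more catalogue regions. Any comparison with EPISC therefore mixes the cell type with the way regions were called.

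Region ends were checked against the chromosome lengths of GRCm38, the assembly behind mm10, and all lay within them. Genes came from GENCODE release M21, with 21829 protein-coding genes. Regions of the 4 lists were merged where they overlapped by at least 1 bp, and a merged region was assigned to every cell type with a region in it. Similarity was the Jaccard index, the bases covered in both lists divided by the bases covered in either, with a 95% interval from 1000 bootstrap draws of 10 Mb blocks and a chance level from 100 circular shifts. A promoter region lay within 1000 bp of a protein-coding transcription start site (TSS), and all others were called distal. Distal regions were assigned to the gene of the nearest TSS within 100000 bp. Shares carry Wilson 95% intervals. All intervals cover counting error or the spread over the genome, not the spread between cultures.

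For 15 gene lists the number of distal regions of a kind was placed as a percentile among 10000 random lists of the same size. These were matched on the decile of the number of distal regions per gene. The highest decile has no upper limit, so matching is loose for genes with many distal regions. A list was called at percentile 99 or above or 1 or below. The lists were naive pluripotency, general pluripotency, primed epiblast, trophoblast, primitive endoderm, fibroblast, neural, mesoderm, germline, haematopoietic, housekeeping, Hox clusters, FGF-ERK feedback, Wnt targets and BMP targets. A random list of 20 genes simulated with no effect was called in 2% of 100 trials for XEN-only regions, and lists with a planted excess of 2-fold were called in 92%. The simulation shuffled the XEN-only label over regions, without the gathering at single genes seen in the data. Its rates therefore do not carry over to the real lists or to the fewer TSC-only regions. For 23 consensus motifs the odds of a match in the central 300 bp were compared by a Mantel-Haenszel odds ratio over 10 strata of GC content, called at 1.5-fold or more with an interval that left out 1. The reversed consensus of each motif served as a composition control where it had enough matches to give a ratio.

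Regions with 2 or more copies in the genome were found by aligning the central 300 bp with minimap2 2.31 to the chromosomes and unplaced scaffolds, without the loci of other strains, and counting places with matches at 90% of the window. Of windows planted again with 8% of their bases changed, 97.8% were found. A first version of the search, which used short-read settings and a target with the loci of other strains, missed planted copies with 3% or more changed bases and counted strain loci as copies. It was replaced after its results had been seen, and the replacement raised the multi-copy share at the genes leading the TSC-only set. Only distal regions were searched. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.

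The rule for genes to name, the 15 lists, the motifs and the thresholds of calls were fixed before the data were examined. The named genes were, per cell type, the 8 with the most specific distal regions, the 4 leading members of each called list, and always Pou5f1, Sox2, Nanog, Esrrb, Klf4, Otx2, Fgf5, Cdx2, Elf5, Eomes, Gata4, Gata6 and Sox17. Alternatives changed the promoter distance, the assignment of regions to genes, the overlap rule, the lengths and widths of lists, the matching of random lists, the similarity measure and the motif window or background. Random lists drawn without matching also reflect how many distal regions of any kind the genes hold. Further alternatives were added after the files had been read: leaving out EPISC, multi-copy regions, narrow EPISC regions or the leading list member, an index over merged regions, a share in place of a number, and runs of neighbouring genes. A second mesenchymal list of 32 genes was drawn up after the AP-1 result and the fibroblast percentile were known, and 0 of its genes stood in another list. The signal tracks that the labels name, which libraries of the same cell type or ESC title share, and the reads were not analysed here. With 1 list per cell type no test between cell types has replicates, so no p-value is given.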

Results

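Accessible chromatin was compared between mouse ESC and EPISC, which stand for naive and primed states of the embryonic lineage, and TSC and XEN cells, which stand for trophoblast and extraembryonic endoderm. The ESC list held 64657 regions covering 12.8 Mb, the EPISC list 61861 regions covering 20.3 Mb, the XEN list 45524 regions covering 9.82 Mb and the TSC list 34973 regions covering 8.11 Mb. The titles name 4 ESC, 3 EPISC, 2 XEN and 3 TSC libraries, but the descriptions and protocol leave open which of them went into these lists. Depth is unknown because the files used here hold no counts, and differences between cell types have no replicate check.

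Most regions were found in 1 cell type or in all 4. Of 112467 merged regions, 27097 were EPISC only, 23391 ESC only, 15130 XEN only and 6779 TSC only, while 13115 were shared by all 4. ESC and EPISC alone shared 11793 regions, and TSC and XEN alone shared 1499. Regions of 1 cell type made up 43.8% of the EPISC set (95% interval 43.4 to 44.2), 41.0% of the ESC set (40.6 to 41.4), 39.0% of the XEN set (38.5 to 39.5) and 23.8% of the TSC set (23.3 to 24.3). Without EPISC, whose regions were called apart from the others, 38840 regions were ESC only. EPISC regions of up to 75 bp lacked overlap with the other lists in 77.8% of cases (76.9 to 78.8), against 39.1% of wider ones (38.7 to 39.6).

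**Figure D1:**
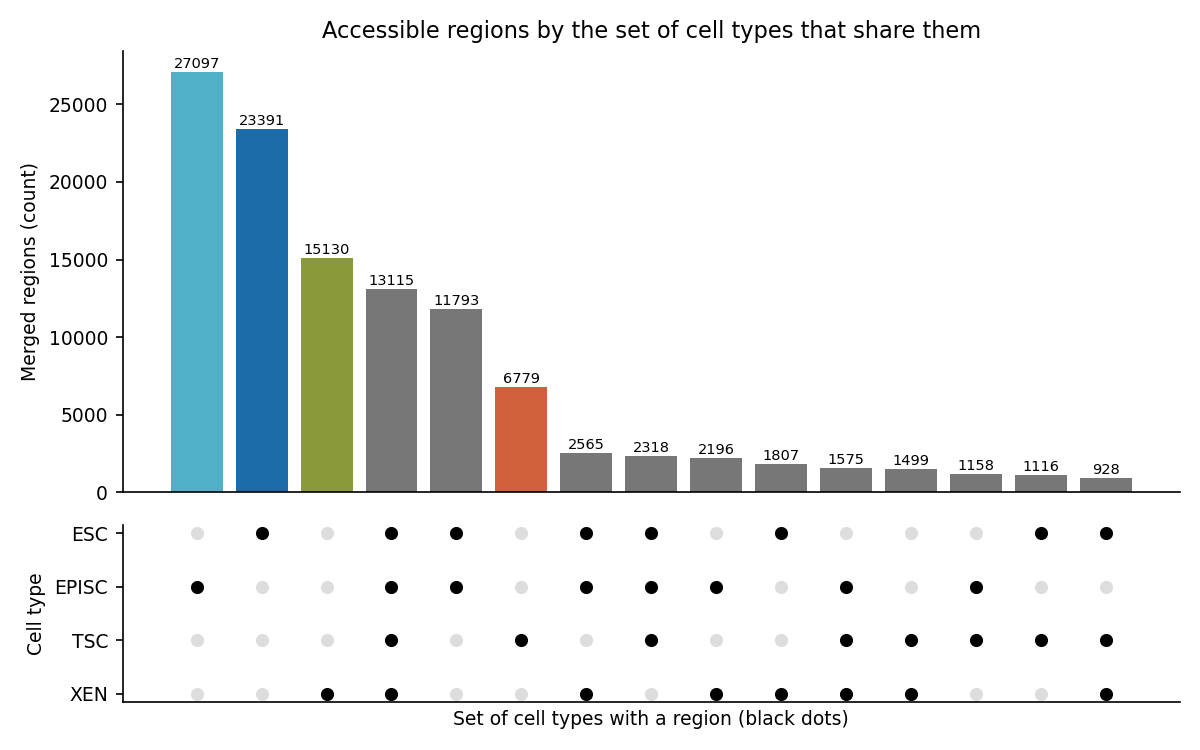
Number of merged regions (bars, from 0) for each set of cell types that has a region there, shown by black dots below. Regions of 1 cell type are coloured, and the highest bars are EPISC only (27097) and ESC only (23391).

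The TSC and XEN lists were the most alike by covered bases. Their Jaccard index was 0.490 (0.479 to 0.5), followed by ESC and TSC at 0.381 (0.370 to 0.391), ESC and XEN at 0.354 (0.344 to 0.363) and ESC and EPISC at 0.276 (0.272 to 0.281). EPISC had lower indices with TSC at 0.241 (0.233 to 0.249) and XEN at 0.230 (0.222 to 0.237). The ESC and EPISC index minus the highest other was -0.213 (-0.222 to -0.205). Among distal regions ESC shared more with EPISC (0.177) than with TSC (0.155) or XEN (0.160), the reverse of the order over all regions. TSC and XEN stayed the highest pair there (0.218), and EPISC was lower with TSC (0.0883) and XEN (0.0933). Among promoter regions ESC and TSC (0.691) and ESC and XEN (0.677) stood above ESC and EPISC (0.445). Randomly shifted lists gave means of 0.00177 to 0.00305. Counted over merged regions rather than bases, ESC and EPISC reached 0.335 and TSC and XEN 0.341, and the difference of -0.0066 (-0.0143 to 0.0012) no longer left out 0. With lists thinned at random to 1 length, EPISC with TSC (0.189) and with XEN (0.146) exceeded ESC and EPISC (0.134). Thinning drops regions from each longer list separately. This by itself lowers the index most for ESC and EPISC, the longest lists, so that order says nothing about the cell types. By the share of the shorter list that overlaps, EPISC and TSC (0.705) were the highest pair, above TSC and XEN (0.610).

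**Figure D2:**
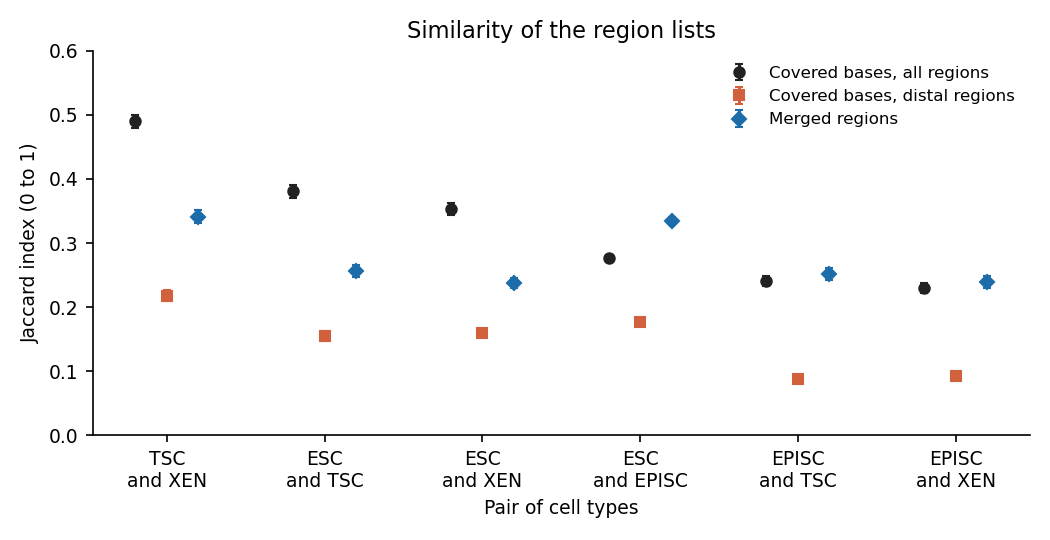
Jaccard index (0 to 1) for each pair of cell types by covered bases, by covered bases of distal regions and by merged regions. Bars are 95% bootstrap intervals over 10 Mb blocks, and the ESC and EPISC pair moves from 0.276 to 0.335 between bases and merged regions.

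TSC regions lay at promoters more often than those of the other cell types. The promoter share was 58.8% in TSC (58.3 to 59.4), 42.5% in XEN (42.1 to 43.0), 30.3% in ESC (29.9 to 30.6) and 24.6% in EPISC (24.2 to 24.9). Introns held 15.7% of TSC, 23.7% of XEN, 27.8% of ESC and 27.3% of EPISC regions. Of regions shared by all 4 cell types, 74.8% (74.1 to 75.6) were promoters, compared with 25.5% of TSC-only regions and 6.83% to 8.03% of regions specific to the other cell types. The number of protein-coding genes with a promoter region was closer, from 12064 in XEN to 13645 in EPISC.

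ESC-only distal regions gathered at genes of naive pluripotency. The list of 19 genes held 115 of them, 2.41 times the mean of 47.7 in matched random lists and above every random list, with regions at 18 genes. Tet2, a DNA demethylase, had 17 ESC-only regions among 22 distal ones, Tfcp2l1 and Klf5, transcription factors of the naive state, had 11 each, and Zfp42 had 10. Tfcp2l1 also had 10 XEN-only regions and Klf5 had 7. The widest ESC-only region of Tet2 lay in an intron at chromosome 3, 133524496 to 133524872 (mm10), and that of Zfp42 lay between genes at chromosome 8, 43320799 to 43321012. Esrrb had 7 ESC-only and 5 EPISC-only regions, and Klf4 had 4 and 1, with 5 XEN-only ones. EPISC-only regions were fewer than in random lists at these genes, 21 against 40.01 (percentile 0.455), among them 5 at Esrrb, 3 each at Nr5a2 and Gbx2 and 2 at Spp1. This lower number passed the threshold neither with the wider 50% of each list (percentile 9.79) nor with lists cut to 1 length (16.9) or a limit of 20000 bp to the TSS (1.15), and random lists not matched on distal regions turned it (86.3). Because matching uses all distal regions, the ESC-only excess by itself can leave fewer regions for EPISC only. Matching was loose at genes with many distal regions, so part of that excess can reflect their total number.

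Counts of ESC against EPISC whatever TSC and XEN held contain the specific sets and largely repeat them at naive genes. Regions in ESC and not EPISC numbered 123 at these genes against 54.9 in random lists (percentile 100), and 115 of them were ESC only. Those in EPISC and not ESC numbered 24 against 47.5 (percentile 0.12), and 21 of them were EPISC only. Primitive endoderm genes held fewer ESC-only regions than matched random lists, 31 against 66.7 (percentile 0.015). Their regions in ESC and not EPISC, which contain those 31, numbered 37 against 76.9 (percentile 0.01). Lamc1 and Foxa2 had 5 ESC-only regions each, Foxa1 had 4 and Lama1 had 3. These lower numbers were no longer called with the wider 50% of each list (percentiles 6.70 for naive genes, 3.54 and 3.81 for primitive endoderm) or lists cut to 1 length (13.3, 8.69 and 13.0), and unmatched random lists turned them (84.8, 83.7 and 87.2). Matching by decile ties the number of all distal regions only roughly to that of the list, and loosely at genes with many of them. The 115 ESC-only regions at naive genes and 139 XEN-only regions at primitive endoderm genes can thus leave fewer for other kinds. The lower numbers cannot be told apart from these excesses.

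EPISC-only distal regions stood out at the Hox clusters, which set position along the body axis. The 39 Hox genes held 25 of them against 13.0 in random lists (percentile 99.98). Regions in EPISC and not ESC, which contain those 25, numbered 27 against 15.6 (percentile 99.94). Hoxb3 and Hoxb1 had 3 EPISC-only regions each, and Hoxa13 and Hoxb13 had 2 each. The widest at Hoxb13 lay between genes at chromosome 11, 96203134 to 96203917, and that at Hoxb3 in an intron at 96332697 to 96333013. Primed epiblast genes held 45 EPISC-only regions against 33.0 (percentile 95.6), with 6 at Otx2 and 4 each at Eomes and Zic3. This was short of a call, but the list was called with a limit of 20000 bp to the TSS (99.1). It was also called with any TSS within 50000 bp (99.4). Against random lists not matched on distal regions the Hox excess turned (percentiles 26.3 and 15.2), and the call in EPISC and not ESC ended without EPISC regions of up to 75 bp (98.9).

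Regions shared by ESC and EPISC but absent from TSC and XEN were more frequent at primed epiblast genes. There were 31 against 15.5 in random lists (percentile 99.79), at 18 of 24 genes, with 4 each at Eomes and Sox4, 3 at Zic3 and 2 at Sox3. Targets of Wnt signalling held 17 against 7.89 (percentile 99.02), including 6 at Lef1, 4 at Tcf7l1 and 2 each at Axin2 and Dkk1. General pluripotency genes were not called for this kind, nor for ESC-only (41 against 33.7) or EPISC-only regions (36 against 29.8). Pou5f1 had 2 distal regions, 1 of them ESC only, Sox2 had 4 ESC-only and 4 EPISC-only regions, and Nanog had 2 and 3. The Wnt call ended in 6 alternatives: without Lef1 (percentile 92.3), with the wider 50% of each list (91.1), lists cut to 1 length (81.5), any TSS within 50000 bp (98.7), by share (98.2) and with a limit of 20000 bp to the TSS (69.1). The primed epiblast call ended with that limit (96.8).

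XEN-only distal regions gathered at genes of primitive endoderm, the lineage XEN cells come from. The 30 genes held 139 against 48.5 in random lists, 2.87 times as many and above every random list. Col4a1, a basement membrane collagen, and the transcription factor Foxa2 had 14 each, and Gata4 and the laminin gene Lamc1 had 13 each. Sox17 had 6 and Gata6 had 3 XEN-only and 5 EPISC-only regions. The widest XEN-only region of Gata4 lay in an intron at chromosome 14, 63231100 to 63231428, and that of Foxa2 between genes at chromosome 2, 148124630 to 148124944. Neural genes held 1 XEN-only region, at Tubb3, against 15.1 in random lists (percentile 0.055), while Ascl1, Dbx1 and Foxg1 had none. Germline genes held 8 against 2.03 (percentile 99.84), 4 at Dazl and 4 at Taf7l, and none at Ddx4 or Hormad1. At promoters XEN had a region at 1 of 12 germline genes, against 2 in EPISC, 5 in ESC and 5 in TSC. The germline call rested on Dazl and Taf7l and ended with a limit of 20000 bp (percentile 60.9), any TSS within 50000 bp (96.7), unmatched random lists (69.5) and without its leading gene (95.3). The neural call ended with the wider 50% of each list (1.82) and unmatched random lists (2.54).

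**Figure D3:**
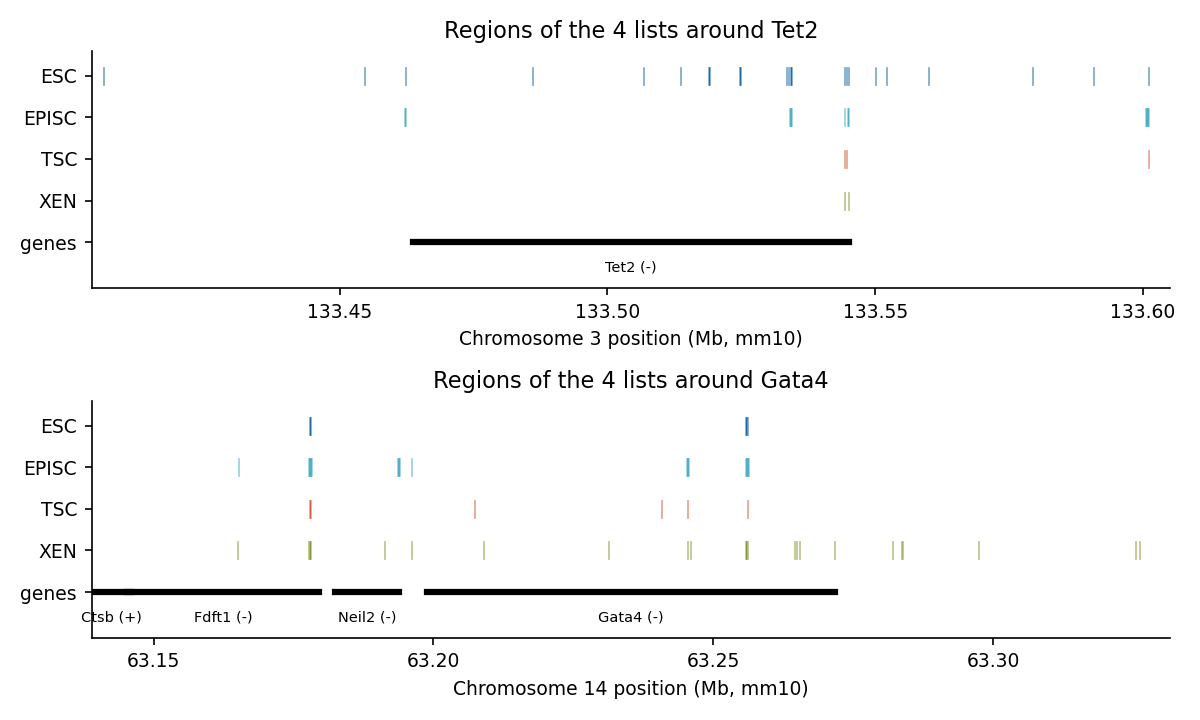
Regions of the 4 lists (coloured bars, to scale) around Tet2 and Gata4 along the chromosome in Mb (mm10), with protein-coding genes in black. The window around Tet2 holds 24 ESC, 6 EPISC, 4 TSC and 2 XEN regions, and that around Gata4 holds 21 XEN, 7 EPISC, 5 TSC and 4 ESC regions.

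TSC-only distal regions were not called at the trophoblast list. Its 30 genes held 18 against 13.0 in random lists (percentile 88.6). Cdx2, Elf5 and Eomes, regulators of trophoblast identity, had no TSC-only distal region, while Cdx2 had 2, Elf5 3 and Eomes 2 ESC-only ones. Of distal regions shared with other cell types, TSC had 4 at Cdx2 and 2 at Eomes, and the Cdx2 promoter had a region in TSC and EPISC and not in ESC or XEN. TSC had no distal region at Elf5, whose promoter had a region in ESC, EPISC and XEN and not in TSC. Fgf5 had 1 TSC-only region. The percentile ranged from 45.6 with lists cut to 1 length to 99.83 with unmatched random lists, which also reflect the number of all distal regions. Fibroblast genes held 7 against 5.35 (percentile 76.2) and mesoderm genes 10 against 5.06 (percentile 96.7). With the EPISC list left out, fibroblast genes held 13 TSC-only regions against 6.06 (percentile 98.5) and mesoderm genes 14 against 6.61 (percentile 98.7).

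**Figure D4:**
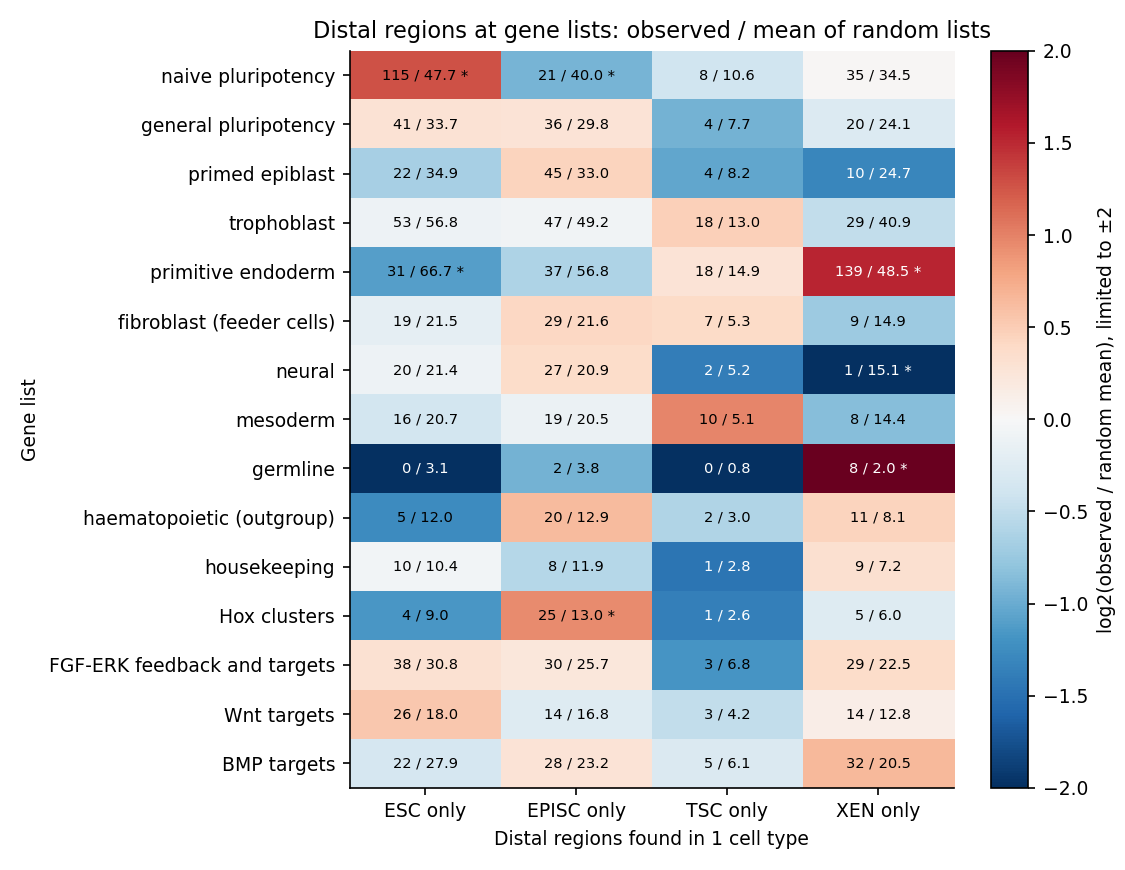
Number of distal regions found in 1 cell type at each gene list, beside the mean of 10000 matched random lists, coloured by the log2 ratio (limited to ±2). Asterisks mark percentile 99 or above or 1 or below, as for naive pluripotency in ESC (115 against 47.7) and primitive endoderm in XEN (139 against 48.5).

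The genes with the most specific distal regions in ESC were Plcb4 with 27, Auts2 with 25, Pde4d with 24, Pawr with 20, Tmem132c and Tenm4 with 19, and Tet2 and Tspan5 with 17. In EPISC they were Pde4d with 21, Nrxn3 with 19, Ndst4, Celf2 and Rbfox1 with 13, and Lmx1b, Anks1b and Rere with 12. In XEN they were Zmiz1 with 17, Palld with 16, Dnm3 with 15, and Col4a1, Lifr, Tcf7l2, Foxa2 and Ston2 with 14. In TSC they were Cwc22 with 11, Sfi1 with 10, Vmn1r2, Dynlt1b and Foxp1 with 7, and Vmn1r238, Otud1 and Apbb1ip with 5. Of these TSC-only regions, 9 of 10 at Sfi1, 5 of 7 at Vmn1r2, 5 of 7 at Dynlt1b and 3 of 5 at Vmn1r238 had 2 or more copies in the reference genome. None at the other 4 genes did. Copy number in the lines used was not measured, so these counts cover the reference only.

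Of 120 combinations of list and kind, 8 were called higher and 5 lower, where 2.4 would be called by chance. The kinds are nested, as ESC not EPISC contains ESC only, so several calls repeat one another and are not separate results. The remaining lists gave no call in the specific sets: haematopoietic genes reached percentile 96.2 in EPISC, housekeeping genes 71.2 in XEN, FGF-ERK feedback genes 81.5 in ESC and BMP targets 92.7 in XEN. At promoters, primed epiblast genes had a region at 23 of 24 genes in EPISC and 18 in ESC, and primitive endoderm genes at 24 of 30 in XEN and 18 in ESC. Trophoblast genes had a region at 19 of 30 in TSC and 24 in EPISC, naive genes at 14 of 19 in ESC and 13 in EPISC, and Hox genes at 19 of 39 in TSC and 16 in EPISC. The Otx2 promoter had a region in EPISC and not in ESC, TSC or XEN.

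Motif content separated the 4 sets of specific distal regions. AP-1 sites, bound by FOS and JUN proteins, were in 51.1% of TSC-only regions and 10.2% of those specific to the others, a log2 odds ratio of 3.32 (3.23 to 3.41). GATA sites were in 28.4% of XEN-only regions against 6.45% (2.50, 2.43 to 2.58). XEN-only regions were also higher for HNF1 (3.77), SOX (0.93) and HNF4A (0.76), which belong to endoderm regulators among others. TSC-only regions were higher for RUNX (0.84) and TFAP2 (0.61, no more than the 0.68 of its reversed consensus), and lower for 11 motifs: the POU5F1-SOX2 composite (-3.52), ESRRB/NR5A2 (-1.48), ZIC (-1.38), OTX2 (-1.31), the POU octamer (-1.29), GATA (-1.28), SOX (-1.15), GRHL (-0.93), FOXA (-0.79), CTCF (-0.71) and T-box (-0.68). XEN-only regions were lower for the composite (-4.69), the POU octamer (-2.19), ESRRB/NR5A2 (-1.64), ZIC (-1.02) and T-box (-0.82). Each background pooled the other 3 sets, so a motif frequent in 1 set made the others lower. GATA was in 4.65% of TSC-only, 5.22% of ESC-only and 7.87% of EPISC-only regions, so its lower calls largely restate the XEN excess. AP-1 was in 5.48% of ESC-only, 10.5% of EPISC-only and 17.2% of XEN-only regions. HNF1 was in 0.517% of XEN-only regions and at most 0.0515% of the other sets.

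ESC-only regions were higher for ESRRB/NR5A2 (1.83, 1.61 to 2.04), the POU5F1-SOX2 composite (1.55, 1.25 to 1.85), KLF (0.75), the POU octamer (0.63) and NRF1 (2.19, 1.11 to 3.26), and lower for AP-1 (-1.84), GATA (-1.50), HNF1 (-2.73) and OTX2 (-0.59). NRF1 matches were rare, in 0.115% of ESC-only regions against 0.023%. The composite was in 0.04% of TSC-only and 0.03% of XEN-only regions, so its ratios there rest on few matches. EPISC-only regions were higher for OTX2 (1.12, 1.03 to 1.2), ZIC (0.99), T-box (0.82), CTCF (0.81) and the POU octamer (0.62), and lower for HNF1 (-2.07), GATA (-0.93), ESRRB/NR5A2 (-0.82), TEAD (-0.67), AP-1 (-0.62) and KLF (-0.61). Between ESC and EPISC directly, ESRRB/NR5A2 (1.45), NRF1 (1.72), the composite (0.88) and KLF (0.80) were higher in ESC, and OTX2 (-1.01), AP-1 (-1.03) and CTCF (-0.75) were lower. CTCF was not called in ESC-only (-0.35) or XEN-only regions (-0.54). Reversed consensus sequences were called for 2 motifs in ESC-only, 3 in EPISC-only, 6 in TSC-only and 1 in XEN-only regions. Those called in the direction of a called motif were AP-1 (1.11), TFAP2 (0.68), GATA (-0.88), OTX2 (-0.81) and GRHL (-0.61) in TSC-only, ESRRB/NR5A2 (0.71) in ESC-only and OTX2 (0.62) in EPISC-only regions. In TSC-only regions the intervals of TFAP2, GATA, GRHL, ESRRB/NR5A2 and ZIC overlapped those of their reversed sequences. So did the composite, the POU octamer and HNF1 in ESC-only regions. The same held for CTCF, ZIC, ESRRB/NR5A2, KLF and HNF1 in EPISC-only regions, and for the composite and CTCF between ESC and EPISC. Some of these reversed intervals were wide. The reversed NRF1 gave no ratio in any comparison, and the reversed composite and CTCF gave none in TSC-only regions. Against regions shared by all 4 cell types, KLF, NRF1 and OTX2 in ESC-only regions and CTCF, ZIC, GATA and ESRRB/NR5A2 in EPISC-only regions changed sign.

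**Figure D5:**
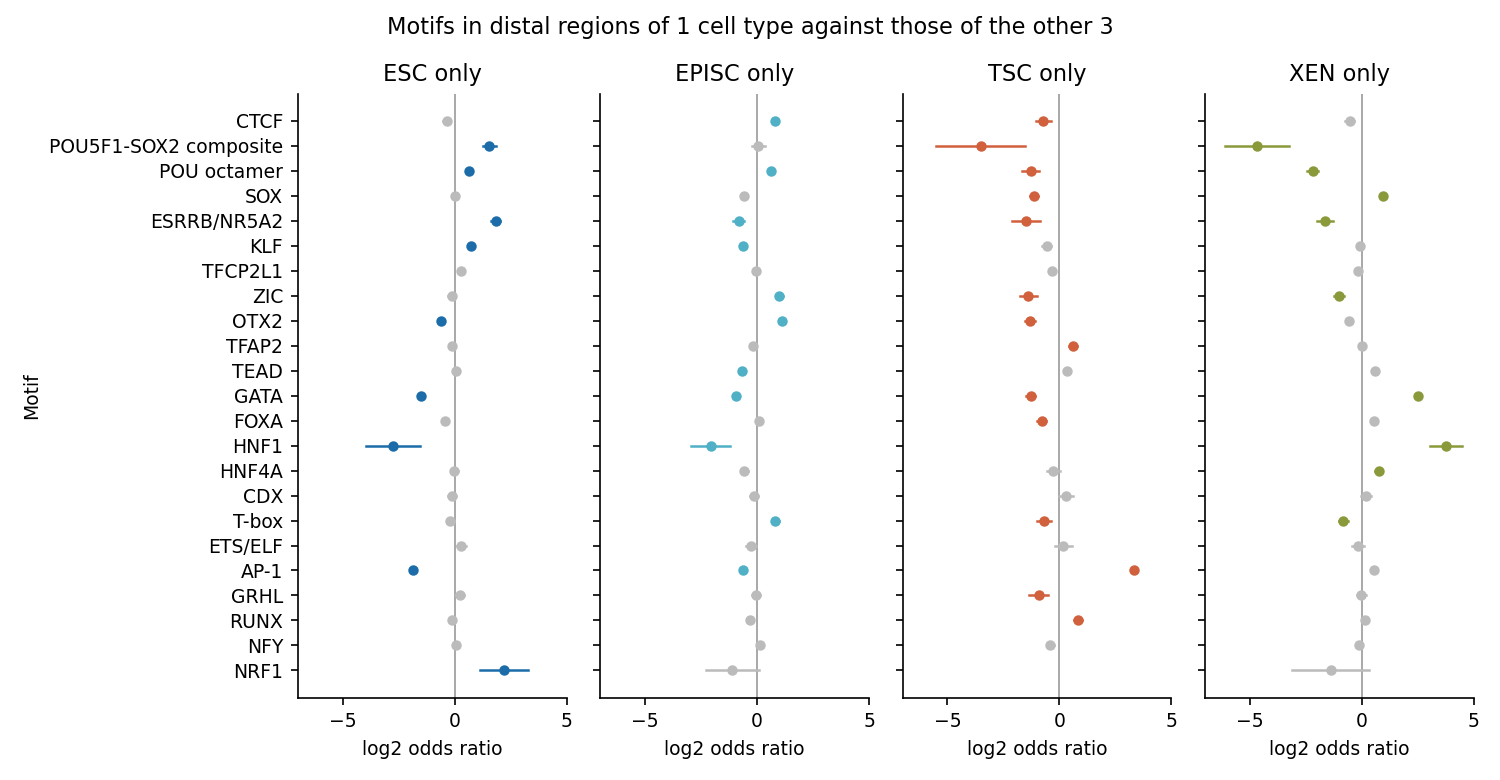
Log2 odds ratio of each motif in distal regions of 1 cell type against those of the other 3, with 95% intervals (lines). Coloured points passed the threshold and grey ones did not, as for AP-1 in TSC (3.32) and GATA in XEN (2.50), while HNF1 and NRF1 had no match in TSC-only regions and have no point there.

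Repeat-derived sequence made up more of the embryonic sets. Soft-masked bases were 24.3% of ESC-only distal regions (23.6 to 25.1) and 22.5% of EPISC-only ones (21.8 to 23.3), compared with 13.1% in XEN-only (12.6 to 13.6) and 9.13% in TSC-only regions (8.58 to 9.78). Regions with 2 or more copies were 7.75% of ESC-only, 5.61% of EPISC-only, 3.53% of XEN-only and 2.45% of TSC-only distal regions.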

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

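The tests chosen only after the result was seen were those of AP-1 sites, the percentile without multi-copy regions and the runs of neighbouring genes, and the copy search was repaired after its first result was known. In TSC-only distal regions 51.1% carried an AP-1 site, the trophoblast list was not called, and 4 of the 8 leading genes had multi-copy regions. Too few TSC-only regions were argued against only for a large excess, since 100 of 100 thinnings of XEN-only regions to the TSC number still called primitive endoderm, at 2.87 times its random mean, against 1.39 for trophoblast. The tests without multi-copy regions (trophoblast at percentile 88.7, its 18 regions all kept) and without dense clusters (AP-1 at 51.6%, where 44.8% was the lowest possible) moved no region of the list or could not reach the other bound, and decide nothing. Multi-copy regions, counted in the reference genome only, were 38.6% (27.1 to 51.6) of 57 at the 8 leading genes, with none at Cwc22, Foxp1, Otud1 and Apbb1ip. This share lay between the bounds set for and against, so that multi-copy sequence cannot be told apart from other causes. Fibroblast feeder cells cannot be told apart from trophoblast regulation, itself untested, since the fibroblast list stood at percentile 76.2 (98.5 without EPISC) and a second mesenchymal list, drawn up after the AP-1 result and 76.2 were known, at 99.6.

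The X chromosome held 1.77% of TSC regions, against 2.57% in XEN, 2.72% in ESC and 2.87% in EPISC. More promoters among TSC regions would raise this share, since promoters held a higher X share than distal regions in each list. In TSC these shares were 2.29% and 1.03%, and in XEN 2.91% and 2.33%. The ratio of the TSC to the XEN share was 0.788 (0.699 to 0.890) within promoters and 0.442 (0.370 to 0.529) within distal regions. The number of promoters thus did not account for the lower share. An inactive X chromosome in a female line was tested by promoter regions at 4 Y-linked genes. TSC had regions at 2 of them, Ddx3y and Eif2s3y, against 2 in ESC, 0 in EPISC and 0 in XEN. Each of the 4 lists held regions on the Y chromosome, 24 in TSC, 15 in ESC, 11 in EPISC and 9 in XEN. Mixed lines or feeder cells could give such regions beside a female line, and promoters were not searched for copies. The test therefore cannot decide. The lines compared could differ in sex and number of X chromosomes, and the TSC list could mix lines, which was not tested. No other biological explanation was tested.

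The Hox excess among EPISC-only distal regions was weighed against the separate and wider calls of the EPISC list. The percentile was 99.55 with the wider 50% of each list and 99.67 with lists cut to 1 length. Both settings keep the widest regions of each list and do not equalise widths between lists. They therefore cannot decide whether the wider EPISC calls are the cause. Neighbouring genes counted as separate were argued against by a percentile of 99.755 among random runs of neighbouring genes. Width and other features of the separate EPISC calls stay open, as does the cell type itself, which the design joins to them.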

How the results depend on the processing

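The settings added only after the results were seen were leaving out EPISC, multi-copy regions, EPISC regions of up to 75 bp or the leading list member, the index over merged regions, the share in place of a number, and runs of neighbouring genes. Of the values that answer a comparison, 236 kept their direction and side of the threshold or size, 35 moved, 24 became weaker, 6 stronger and 8 reversed, and the cause was not tested except where a setting by its construction shortens the lists. No paired analysis was possible because the files used here hold 1 list per cell type and no values per library. Signal tracks and reads were not analysed here, so leaving out replicates was not done. Of other values, 160 stayed the same, 42 moved, 35 became weaker, 3 stronger and 7 reversed. Depth is unknown and limits every number of regions. For 2 motif values an alternative left no match in 1 set and gave no value.

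With a gap of up to 500 bp counted as shared, TSC and XEN alone shared 932 regions and 9 combinations of list and kind were called lower. With the wider 50% of each list, specific regions were 9983 (ESC), 14608 (EPISC), 765 (TSC) and 4488 (XEN), with 13876 in ESC not EPISC, 15604 in EPISC not ESC, 3792 in ESC and EPISC alone and 969 in TSC and XEN alone. In that setting 3 combinations of list and kind were called lower. Percentiles were 9.79 and 6.70 for naive genes (EPISC only, EPISC not ESC) and 3.54 and 3.81 for primitive endoderm (ESC only, ESC not EPISC). They were 1.82 for neural (XEN) and 91.1 for Wnt targets. With lists cut to the shortest by width, regions were 9914 (ESC), 14496 (EPISC), 14579 (ESC not EPISC), 18085 (EPISC not ESC) and 3759 (ESC and EPISC alone). There 3 combinations of list and kind were called lower. Naive genes stood at 16.9 and 13.3, primitive endoderm at 8.69 and 13.0, Wnt targets at 81.5 and trophoblast in TSC reversed at 45.6. With lists thinned at random, 10596 regions were TSC only, 4024 ESC and EPISC alone, 4870 TSC and XEN alone and 3852 in all. Without EPISC 38840 were ESC only. Over merged regions the difference in index was -0.00656.

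With promoters within 500 bp the shares were 27.6% (ESC), 22.2% (EPISC), 55.2% (TSC) and 39.5% (XEN), and within 2500 bp 33.8%, 28.2%, 61.7% and 46.3%. Against unmatched random lists, which also reflect how many distal regions of any kind the genes hold, 33 combinations of list and kind were called higher. Percentiles then reversed for naive genes (86.3 and 84.8), primitive endoderm (83.7 and 87.2) and Hox clusters (26.3 and 15.2). They rose for general pluripotency (99.5), primed epiblast (99.93 EPISC only, 99.94 EPISC not ESC) and trophoblast (99.8), and weakened for neural (2.54) and germline (69.5). With any TSS within 50 kb 11 combinations were called lower, with primed epiblast in EPISC at 99.4, germline at 96.7 and Wnt targets at 98.7. With the nearest TSS within 20 kb, naive genes in EPISC stood at 1.15, primed epiblast at 99.1 in EPISC and 96.8 in ESC and EPISC, germline at 60.9 and Wnt targets at 69.1. Without the leading member 10 combinations were called lower. General pluripotency was reversed at 41.0 in ESC and EPISC alone, germline stood at 95.3 and Wnt targets at 92.3. General pluripotency then also stood at 40.6 in ESC only, from 81.4, and at 38.6 in ESC not EPISC, from 79.8. By share, Wnt targets stood at 98.2, and without EPISC regions of up to 75 bp Hox clusters in EPISC not ESC at 98.9.

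Against regions shared by all 4, log2 odds ratios reversed for KLF (-0.22), OTX2 (0.10) and NRF1 (-0.72) in ESC and for CTCF (-2.29), ESRRB/NR5A2 (0.53), ZIC (-0.56) and GATA (0.29) in EPISC, where 7 motifs were called. Searching whole regions called 11 motifs between ESC and EPISC.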
